A study of Mus musculus with 4 samples.

How the data were processed

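Single-cell RNA-seq of 4 mouse libraries was analysed: tumour and tumour-draining lymph node (TDLN), each with NanoCa and with mock treatment, 1 library per group. The groups follow the sample names and the treatment tag, which reads no treatment for the mock libraries, while the treatment protocol field names NanoCa for all 4 libraries. That conflict could not be settled here, and every NanoCa to mock ratio rests on the names and tags being right. Per the labels, dissociated tissue was stained with a CD45 antibody and sorted by flow cytometry before 10x Genomics 3' v2 libraries were made; the gate is not given in the sources used here, and all 4 libraries carry a single batch date. The deposited values are raw UMI counts per gene and cell barcode, 31253 genes in each library. Per the file headers, the authors made them with Cell Ranger 7.1.0, and the submitters' processing notes also name Cell Ranger. The genome build and annotation release are not given in the sources used here, so genes are named by symbol and Ensembl identifier without coordinates. GENCODE vM21 was used by gene identifier for GC content alone. The number of mice behind each library is not given in the sources used here.

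Barcodes with at least 200 genes and at most 10% of UMIs from mitochondrial genes were kept. Doublet scores came from Scrublet as implemented in scanpy 1.11.5, run per library, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes. This left 10201 cells of tumour NanoCa, 8586 of tumour mock, 10036 of TDLN NanoCa and 9417 of TDLN mock. The libraries of a tissue were clustered together without integration. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken with library as batch key. Mitochondrial, ribosomal, hemoglobin, immunoglobulin and T-cell receptor variable genes, Xist, Y-linked genes and the interferon, cell cycle and stress lists were left out of the clustering genes. Clustering used 30 principal components, 15 exact neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). It gave 33 tumour and 29 TDLN clusters. T cells were clustered again with 20 components.

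Clusters were named from 18 class marker lists and 7 T subset marker lists. A name needed at least 3 markers of the class enriched 1.5-fold or more over the other clusters, and clusters without a clear name stayed unnamed. A further rule was set after the data were seen. Clusters whose Ptprc and Xist levels were both under 20% of the median of the named immune clusters were called Xist-low Ptprc-low cells, 13 clusters in the tumour and 3 in TDLN. It replaced the marker-based name of 1 TDLN cluster (fibroblast, 7 markers enriched). In the tumour, the best-scoring class of 1 of these clusters was plasmacytoid DC. With 1 marker enriched, that cluster had no name to replace.

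Shares of kept cells carry exact Clopper-Pearson 95% intervals. Ratios of shares carry exact conditional binomial 95% intervals on the log2 scale. Shares are also given without the classes that lack Ptprc (Xist-low Ptprc-low cells, fibroblasts, endothelial and epithelial cells). For classes with at least 100 cells in each library of a tissue, UMIs were summed per library and class and expressed as CPM of the class sum. Levels carry exact Poisson 95% intervals and NanoCa to mock ratios exact conditional binomial 95% intervals. A gene with at least 50 UMIs over both libraries was called higher or lower where the interval excluded a ratio of 1 and CPM differed at least 1.5-fold. A gene at 0 in a library was compared with a floor of 3 counts in that library. Cells are not replicates, so no test was run, no p-value is given, and every interval covers counting error alone.

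For each of 21 gene lists, the median log2 ratio of the members with at least 50 UMIs was compared with 10000 random lists of the same size, matched in 20 bins of expression, and its position among them is given as a percentile. The interval of a median comes from 1000 redraws of the counts. The lists cover interferon-stimulated genes, interferon-gamma-induced genes, interferons with their receptors and nucleic-acid sensors, MHC class I presentation, MHC class II presentation, dendritic cell maturation, cytotoxic effectors, inhibitory receptors and exhaustion, naive and memory T cells, regulatory T cells, inflammatory myeloid genes, tissue-repair and suppressive myeloid genes, chemoattractants, calcium signalling, endoplasmic-reticulum stress, inflammasome and lytic cell death, lysosome and lipid handling, glycolysis and hypoxia, cell cycle, germinal-centre and activated B cells, and immediate-early genes. The comparisons, marker lists, gene lists, cell filters, calls and the rule for named genes were fixed before the data were examined.

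Named genes were, in the 3 largest classes of each tissue, the 4 with the highest and the 4 with the lowest ratio, ranked by the interval bound nearest to 1, among genes with at least 50 CPM in a library. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, T-cell receptor, Xist and Y-linked genes, unnamed gene models and markers of other classes were left out. So were genes whose CPM was under 0.1 of that in another class with at least 50 cells. Up to 4 members per described list were named as well, together with Ifnb1 and Ifng. Cells with Ifnb1 were counted in every class after its summed levels were seen. Certain genes are not reported here.

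The share of free RNA in a class was read from Rhox5 and keratin genes (Krt18, and in the tumour Krt20) of the Xist-low Ptprc-low cells, as their CPM in the class over their CPM in all kept cells of the library. These source genes were picked after the data were seen. For NanoCa and mock the share was 29.5% and 24.2% in tumour T cells, 27.7% and 26.4% in tumour B cells, 14.8% and 15.5% in tumour NK cells and 12.3% and 12.4% in tumour monocytes and macrophages. In TDLN it was 8.70% and 11.8% in T cells, 10.2% and 14.4% in B cells, 11.7% and 9.43% in NK cells, 12.5% and 10.2% in monocytes and macrophages and 8.86% and 7.30% in mature DC. In smaller tumour classes it was 67.3% and 100.0% in fibroblasts, which held keratin genes themselves, 57.8% and 58.5% in neutrophils, 49.1% and 25.7% in endothelial cells and 52.9% in plasmacytoid DC with NanoCa. Levels and ratios are printed without subtracting it unless stated. Alternatives fixed in advance were mitochondrial limits of 5% and 20%, at least 500 genes per cell, no doublet removal, Scrublet's automatic threshold, resolutions of 0.5 and 2, all variable genes used, separate clustering of each library, TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, list members with at least 10 UMIs or at least 1 UMI, and cells thinned to 1000 UMIs. Chosen after seeing the data were free RNA subtraction, equal cluster makeup in both libraries, leaving out the cytotoxic CD8 T subset, leaving out unnamed clusters, T clustering without cytotoxic and exhaustion genes, and a ranking of genes relative to the other classes. Which lists, shares and genes were followed through the alternatives was also decided after their values were seen.

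The calls were tested on simulated data, with summed counts drawn from a Poisson model at the depth of 500 cells per group and ratios set in 200 genes. All simulated 3-fold changes and at least 97.0% of 2-fold changes were called, while 1.5-fold changes were called in 47.1% to 69.7% of genes. Of unchanged genes, 107 of 9978 in the tumour setting and 115 of 9744 in the TDLN setting were called. The model holds no spread between cells or libraries, so these rates cover counting error alone and can be higher in the real data. Simulated depth was that of 500 average kept cells, and ratios were set only in genes expected above the limit of 50 UMIs. Small classes held fewer UMIs, such as tumour NK cells (759322 with NanoCa, 1174465 with mock) and TDLN mature DC (931298 and 1117511). The shares of changes called do not apply to such classes or to genes near that limit. Other software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.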

Results

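Sorted cells of CT26 tumours, grown from a mouse colon carcinoma line, and of their draining lymph nodes (TDLN) were profiled by single-cell RNA-seq. NanoCa is described in the series title as a lipid nanoparticle with a calcium crystal, meant for immunotherapy through interferon beta. The 4 groups (tumour NanoCa, tumour mock, TDLN NanoCa and TDLN mock) held 1 library each, so there is no replicate and each interval given covers counting error alone. The tumour libraries held 167924801 UMIs over 11287 barcodes (NanoCa) and 148121144 over 9404 (mock), with medians of 12387 and 11934.5 UMIs per barcode. The TDLN libraries held 74909974 UMIs over 11072 barcodes (NanoCa) and 106579362 over 10400 (mock), with medians of 4230.5 and 4417. After filtering, 10201, 8586, 10036 and 9417 cells were compared. The mock libraries are tagged as untreated, but their treatment protocol field names NanoCa, a conflict that the labels leave open and that bears on every ratio. Class names stand for clusters that resemble the class by their markers, ratios are NanoCa over mock on the log2 scale, and levels are CPM, the UMIs of a gene scaled to the summed UMIs of a class.

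The tumour comparison addressed how NanoCa altered the cells of treated tumours relative to mock. T cells were a smaller share of kept cells with NanoCa, 7.49% (95% interval 6.99 to 8.02, 764 cells) against 11.2% (10.5 to 11.8, 958 cells), a log2 ratio of -0.58 (-0.71 to -0.44). NK cells, innate killers of tumour and infected cells, were also lower, 1.99% against 3.12% (log2 -0.65, -0.92 to -0.38), as were neutrophils, 0.853% against 1.47% (log2 -0.78, -1.19 to -0.38). B cells were higher, 4.61% against 3.14% (log2 0.55, 0.33 to 0.77). Plasmacytoid dendritic cells (DC), known producers of type I interferon, made up 0.716% against 0.338% (log2 1.08, 0.44 to 1.76). Mature DC, the migratory antigen-presenting state, made up 0.461% against 0.175% (log2 1.40, 0.53 to 2.34) on 47 and 15 cells, and the log2 ratio was 0.74 at resolution 0.5. Fibroblasts were higher at 1.66% against 0.932% (log2 0.83, 0.44 to 1.23), with a log2 ratio of 0.55 when each library was clustered on its own. That class also held the keratin genes Krt18 (188 CPM with NanoCa, 534 with mock) and Krt8 (140.2 and 377 CPM) of epithelial cells, at levels that differed between the libraries. Monocytes and macrophages made up 9.74% against 8.37% (log2 0.22, 0.079 to 0.36), and the log2 ratio was 0.049 with that same separate clustering.

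Most kept tumour cells, 66.4% with NanoCa and 67.7% with mock (log2 -0.027, -0.078 to 0.024), lay outside the immune classes. Cells were sorted after a CD45 stain, and the gate is not given. These Xist-low Ptprc-low cells had 2.35 and 2.85 CPM of Ptprc, the gene of CD45, against 547 and 557 CPM in T cells. Their most populated cluster held 14.5% of them with NanoCa, and a different cluster held 13.5% with mock. Without the classes that lack Ptprc, the T cell share was 24.1% with NanoCa and 36.3% with mock (log2 -0.59, -0.73 to -0.45).

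**Figure D1:**
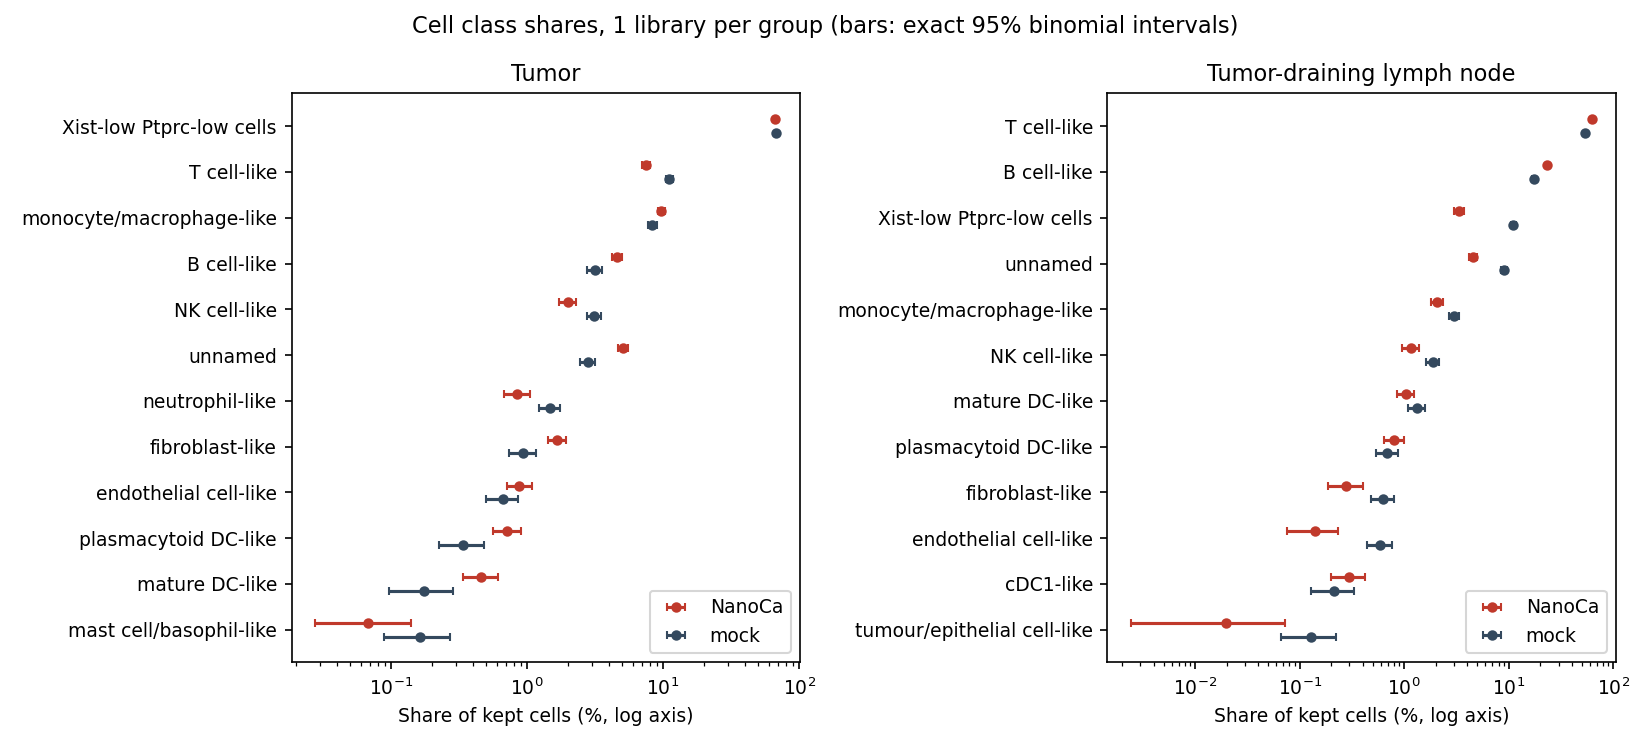
Share of kept cells in each class (percent, log axis) for tumour and TDLN, with NanoCa in red and mock in dark blue; points are single libraries and bars are exact 95% binomial intervals. In the tumour, T cells were at 7.49% with NanoCa and 11.2% with mock, and in TDLN Xist-low Ptprc-low cells were at 3.38% and 11.1%.

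Tumour T cells held lower levels of cytotoxic genes with NanoCa. Granzymes, the proteases that killer lymphocytes deliver into target cells, were lower: Gzmb (ENSMUSG00000015437) was at 124 against 390 CPM (log2 -1.65, -1.87 to -1.44), Gzmf (ENSMUSG00000015441) at 4.56 against 84.0 CPM (log2 -4.20, -5.43 to -3.20), and Gzme at 20.5 against 70.7 CPM (log2 -1.79, -2.34 to -1.27). The serpin gene Serpinb9b was at 9.12 against 59.2 CPM (log2 -2.70, -3.54 to -1.96). Of 25 measured cytotoxic effectors, 16 were lower, 1 was higher and 8 were neither, with a median of -0.70 (-0.85 to -0.59) that lay below all 10000 random lists. Among them were the NK-type receptor genes Klrc1 (log2 -1.56) and Klrk1 (log2 -1.38). Ifng, the gene of interferon gamma, was at 82.6 against 124 CPM (log2 -0.59, -0.88 to -0.31). Of 15 genes of inhibitory receptors and exhaustion, 9 were lower and 0 higher, median -0.62 (-0.76 to -0.47), also below all random lists. They included Pdcd1, which encodes the checkpoint receptor PD-1, at 94.0 against 203 CPM (log2 -1.11, -1.37 to -0.86), and the transcription factor gene Nr4a2 (log2 -0.86).

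These lists moved with the makeup of the T cells, and free RNA was estimated at 29.5% of their profiles with NanoCa and 24.2% with mock. Lists named for other cell types also moved: tissue-repair myeloid genes had a median of 0.28, germinal-centre and activated B-cell genes 0.25 and inflammatory myeloid genes -0.21. T cells can express some of these genes themselves, so the medians alone do not show whose RNA moved. Cytotoxic effectors were as low in tumour B cells (median -0.69, 3 of 6 lower). In tumour NK cells 1 of 23 was higher and 0 lower (median -0.11, -0.17 to -0.0025), and the median was -0.55 without doublet removal. Gzme had a median log2 ratio of 1.00 over the other tumour classes, opposite to T cells. Cytotoxic CD8 T cells made up 4.19% (2.88 to 5.86, 32 cells) of tumour T cells with NanoCa and 12.4% (10.4 to 14.7, 119 cells) with mock, a log2 ratio of -1.57 (-2.18 to -0.99). Without that subset, the medians were 0.17 for cytotoxic effectors and 0.19 for exhaustion genes, and with the same cluster makeup in both libraries they were -0.072 and -0.31 (settings chosen after the data were seen). In cells thinned to 1000 UMIs, the cytotoxic median was -0.35. Regulatory T cells, which restrain immune responses, made up 7.85% against 5.01% of T cells (log2 0.65, 0.077 to 1.23). Of 13 regulatory T-cell genes in T cells, 4 were higher and 0 lower (median 0.18, 0.055 to 0.33, percentile 97.0), among them Izumo1r (log2 1.08) and Il2ra (log2 0.67), a subunit of the interleukin 2 receptor. Shares of naive, CD4 and other CD8 T cells had intervals that included a ratio of 1. The naive class joined clusters of opposite direction, 304 against 119 cells in cluster 0 and 70 against 321 in cluster 1.

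Tumour monocytes and macrophages had lower inflammatory cytokine levels with NanoCa. Tnf (ENSMUSG00000024401) was at 196 against 760 CPM (log2 -1.95, -2.05 to -1.86), Il1a at 134 against 487 CPM (log2 -1.86, -1.97 to -1.74), and Nlrp3, the inflammasome sensor, at 116 against 345 CPM (log2 -1.57, -1.70 to -1.44). The costimulatory ligand gene Tnfsf9 was also lower (log2 -1.82, -2.00 to -1.65). Of 25 inflammatory myeloid genes, 16 were lower and 0 higher, with a median of -0.75 (-0.999 to -0.72) below all random lists. Of 20 interferon-gamma-induced genes, 6 were lower and 1 higher, median -0.40 (-0.50 to -0.33), with Irf1 at log2 -1.08 and Cd274, which encodes PD-L1, at -0.81. Of 17 chemoattractants, 5 were lower and 0 higher, median -0.46 (-0.47 to -0.39), including the neutrophil attractants Cxcl1 (log2 -1.50) and Cxcl2 (log2 -1.36). MHC class II genes had a median of -0.50 (-0.56 to -0.32), with 3 of 11 lower, among them Cd74 (log2 -0.60), and the median was -0.21 with at least 10 UMIs per member and -0.32 with the same cluster makeup. Glycolysis and hypoxia genes had a median of -0.33 (-0.37 to -0.28) and immediate-early genes one of -0.32, each below all random lists. Retnla (ENSMUSG00000061100), a gene of alternatively activated macrophages, was higher at 176 against 3.73 CPM (log2 5.56, 4.94 to 6.26). Of 28 tissue-repair genes, 4 were higher and 3 lower, median 0.21 (0.17 to 0.26) above all random lists. The higher ones included Gpnmb (log2 1.76), while Hmox1 (log2 -1.22) and Il10 (log2 -1.49) were lower. The tissue-repair median was 0.13 with TMM and 0.14 with median-of-ratios scaling, and 0.32 in thinned cells. Some lists named for lymphocytes were lower in this class, cytotoxic effectors at a median of -0.45 (3 of 12 lower, 0 higher) and germinal-centre and activated B-cell genes at -0.16 (5 of 15 lower, 0 higher). The first shares Tnf, Ccl3 and Ccl4 with the inflammatory myeloid list. The second shares Cd86 with that list and Egr1, Nr4a1 and Cd69 with the immediate-early list. These medians thus need not come from lymphocyte RNA. Naive and memory T-cell genes were at 0.30 (-0.0499 to 0.40, percentile 96.6), with 1 of 11 higher and 1 lower. Regulatory T-cell genes were at 0.18 (-0.0052 to 0.33, percentile 84.4), with 1 of 5 lower and 0 higher. Both of these intervals included no change.

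In the tumour, Xist-low Ptprc-low cells held lower levels of genes induced by interferon gamma. Of 23 such genes, 18 were lower and 1 higher, with a median of -1.03 (-1.09 to -0.96) below all random lists. Gbp2 (ENSMUSG00000028270), an interferon-induced GTPase, was at 73.3 against 181 CPM (log2 -1.30, -1.34 to -1.27), and Iigp1 and Gbp4 were both at log2 -1.47. Of 22 MHC class I presentation genes, 3 were lower and 0 higher, median -0.41 (-0.43 to -0.37) below all random lists, with the immunoproteasome subunit gene Psmb9 at 61.6 against 118 CPM (log2 -0.94, -0.98 to -0.90). Of lists of immune cells in this class, inflammatory myeloid genes were at a median of -0.58 (12 of 25 lower, 0 higher), MHC class II genes at -0.35, cytotoxic effectors and chemoattractants each at -0.33, and tissue-repair genes at 0.12 (3 of 27 higher, 1 lower). Ly6a (log2 -1.11) and the laminin gene Lama2 (log2 -1.23) were also lower. Of 50 interferon-stimulated genes, 4 were lower and 0 higher, median -0.25 (-0.28 to -0.22), and the median was -0.16 with the same cluster makeup. Cell cycle genes had a median of 0.16 (0.14 to 0.16), above all random lists, which was 0.041 with the same cluster makeup.

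Ifnb1 (ENSMUSG00000048806), the gene of interferon beta named in the series title, was rare. In tumour monocytes and macrophages it had 5 UMIs with NanoCa and 35 with mock (0.834 against 6.22 CPM, log2 -2.90, -4.61 to -1.54). Those UMIs lay in 2 cells with NanoCa and 21 cells with mock. In tumour Xist-low Ptprc-low cells it had 50 UMIs in 8 cells with NanoCa, 23 of them in a single cell, and 9 UMIs in 9 cells with mock. Its highest level, 33.7 CPM, was in plasmacytoid DC of tumour NanoCa, where 12 UMIs lay in 1 of 73 cells of a class with 52.9% free RNA by the keratin and Rhox5 estimate, against 1 UMI among 29 cells with mock. It had 1 and 0 UMIs in tumour T cells, and 0 in NK and B cells of both tumour libraries. Interferon-stimulated genes, its usual targets, were higher in tumour NK cells with NanoCa, with 10 of 36 higher and 1 lower, median 0.34 (0.23 to 0.48) above all random lists. Examples were Ifit1 (log2 1.21) and Usp18 (log2 0.92), and the median was -0.10 without doublet removal. Lists named for other cell types were also higher in these NK cells, MHC class II genes at a median of 0.76 and germinal-centre and activated B-cell genes at 0.38. In T cells, 4 of 44 were higher and 1 lower, median 0.15 (0.098 to 0.28, percentile 98.3), which was 0.079 and 0.073 with the other scalings and 0.28 with free RNA subtracted. In monocytes and macrophages, 1 of 50 was higher and 3 were lower, with a median of -0.0062 (-0.023 to 0.085, percentile 3.21) that ran from -0.089 to 0.11 over the alternatives. In B cells, 2 of 18 were higher and 0 lower, median 0.095 (-0.084 to 0.29, percentile 71.0), and the alternatives ran from -0.31 to 0.34.

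The genes highest with NanoCa in the tumour were mostly higher in every class. Of 4080 genes measured in all 5 compared classes, 81 were higher in all and 2 were lower in all. They included Pcbd2 (63.2 against 7.94 CPM in T cells, log2 2.99, 2.32 to 3.73), the transcription initiation factor gene Taf10 (log2 2.48 in T cells), the iron-sulfur cluster scaffold gene Iscu (log2 2.63 in T cells), Srm, which encodes spermidine synthase (log2 2.73 in Xist-low Ptprc-low cells), Bri3 (log2 2.65 in monocytes and macrophages), B3gnt2, Rab5if and Tmem160. Glrx5, of iron-sulfur cluster assembly, was at log2 3.24 in Xist-low Ptprc-low cells. In T cells of TDLN, 29 of the 81 were lower with NanoCa and 0 were higher.

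**Figure D2:**
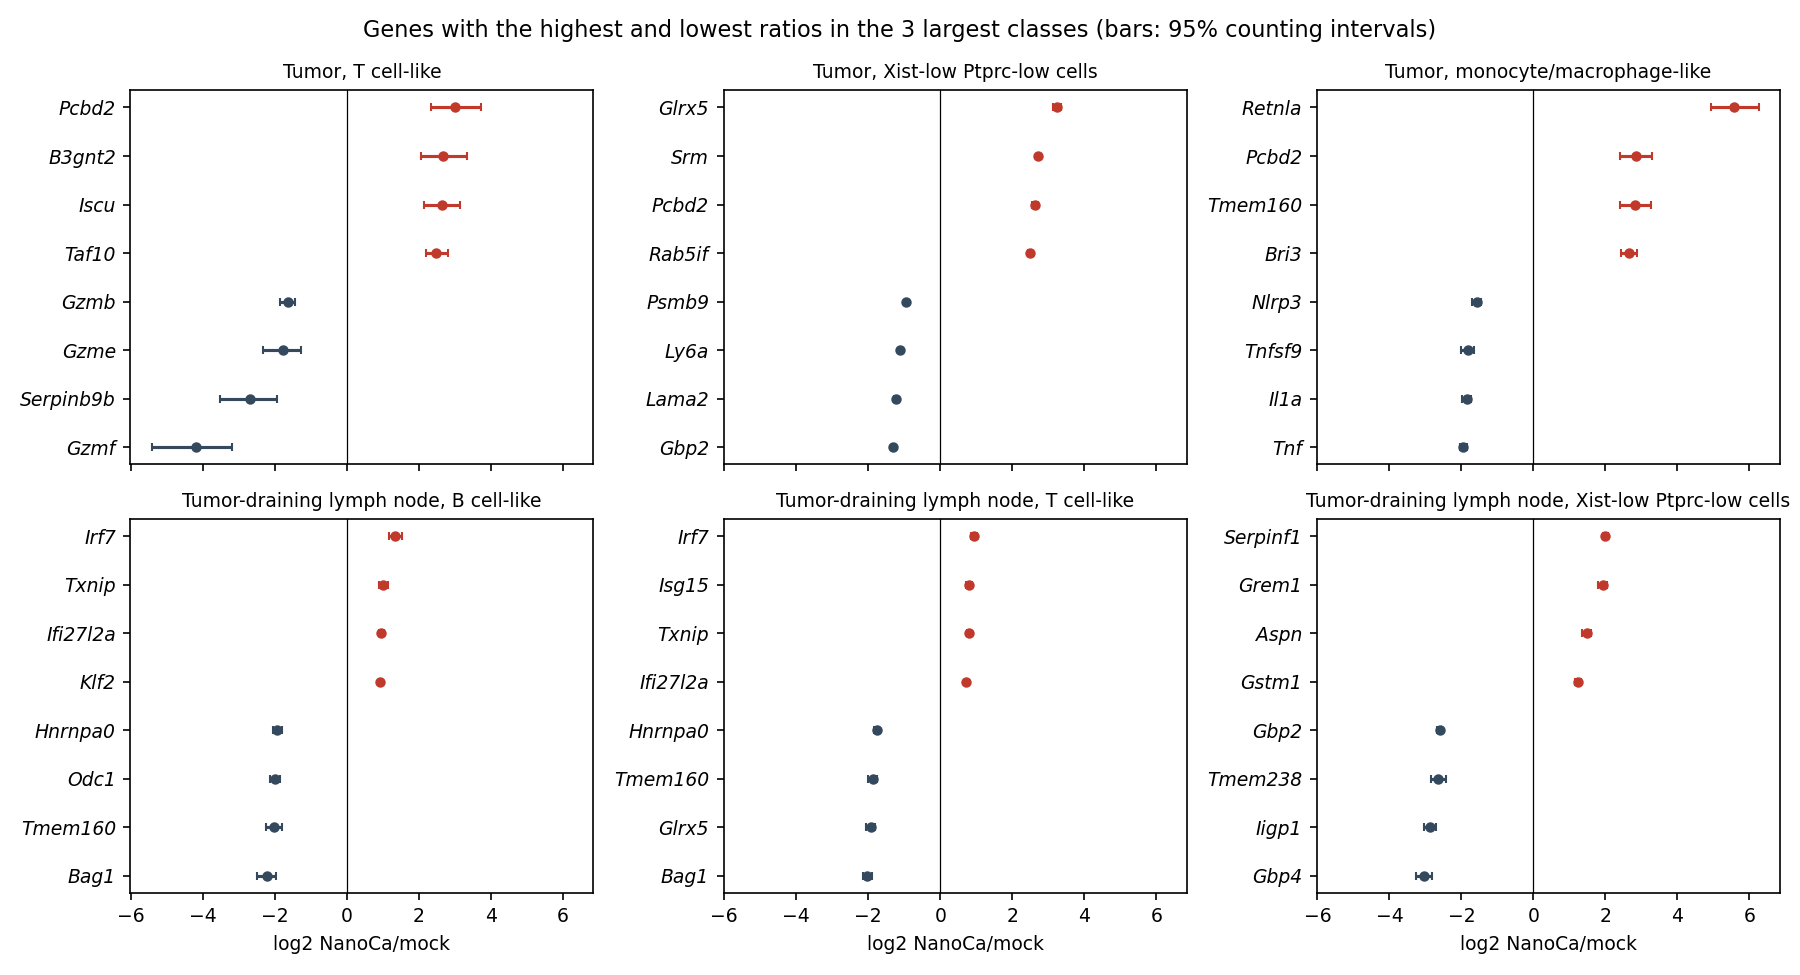
Log2 ratio of CPM, NanoCa over mock, for the genes with the highest and lowest ratios in the 3 largest classes of tumour (top) and TDLN (bottom); points are single ratios, red above 0 and dark blue below, and bars are 95% counting intervals. Retnla stands at 5.56 in tumour monocytes and macrophages, and Gzmf at -4.20 in tumour T cells.

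The TDLN comparison addressed how NanoCa altered the nodes that drain the tumour, where antigen is presented to lymphocytes. Lymphocytes were a larger share of kept cells with NanoCa, T cells at 62.9% (62.0 to 63.9) against 54.1% (53.0 to 55.1, log2 0.22, 0.17 to 0.27) and B cells at 23.4% against 17.4% (log2 0.43, 0.33 to 0.52). Xist-low Ptprc-low cells were lower at 3.38% (3.03 to 3.75, 339 cells) against 11.1% (10.4 to 11.7, 1043 cells), log2 -1.71 (-1.89 to -1.54), in a sort whose CD45 gate is not given. NK cells were at 1.16% against 1.87% (log2 -0.69, -1.04 to -0.35). Monocytes and macrophages were at 2.06% against 3.01% (log2 -0.54, -0.81 to -0.28), and the log2 ratio was -1.12 at resolution 0.5. Fibroblasts were at 0.279% against 0.627% (log2 -1.17, -1.87 to -0.50) and endothelial cells at 0.139% against 0.584% (log2 -2.07, -3.03 to -1.20). Without the classes that lack Ptprc, T cells were at 65.4% against 61.7% (log2 0.084, 0.030 to 0.14). On the same footing B cells were at log2 0.29 (0.20 to 0.38), and mature DC at -0.48 (-0.87 to -0.093), while over all kept cells the interval of mature DC included a ratio of 1. The smaller denominator still held unnamed cells, 4.71% with NanoCa against 10.3% with mock, so these ratios also depend on them. Among them was cluster 6 (185 and 415 cells), with Ptprc at 123 CPM and Rhox5 at 261 CPM.

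Interferon-stimulated genes were higher in T and B cells of TDLN with NanoCa. In B cells, 19 of 45 were higher and 0 lower, median 0.53 (0.44 to 0.64), and in T cells 17 of 49 were higher and 2 lower, median 0.48 (0.42 to 0.53), each above all random lists. Myeloid lists, many of whose genes B and T cells do not express much, were lower in the same classes. Medians in B and T cells were -1.56 and -0.92 for chemoattractants, -1.18 and -0.68 for tissue-repair genes, and -0.50 and -0.47 for inflammatory myeloid genes. Free RNA was estimated at 10.2% with NanoCa and 14.4% with mock in B cells, and at 8.70% and 11.8% in T cells. RNA of other cell types was thus part of these profiles, but its part in these medians was not tested. Irf7 (ENSMUSG00000025498), a regulator of type I interferon responses, was at 130 against 51.5 CPM in B cells (log2 1.34, 1.16 to 1.52) and 113 against 58.9 CPM in T cells (log2 0.94, 0.85 to 1.02). Ifi27l2a was higher in B cells (log2 0.94) and T cells (log2 0.70), Isg15, a ubiquitin-like modifier, in T cells (log2 0.80, 0.71 to 0.89), Ifit3 in B cells (log2 2.39) and Ifit1 in T cells (log2 1.94). Txnip, an inhibitor of thioredoxin, was higher in B cells (log2 1.01) and T cells (log2 0.79), and Klf2, a factor of lymphocyte quiescence and trafficking, in B cells (log2 0.92, 0.87 to 0.96). With all variable genes used for clustering, the list medians were 0.23 in T cells and 0.13 in B cells, and with free RNA subtracted that of B cells was 0.85.

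TDLN T cells had lower levels of cytotoxic genes with NanoCa. Of 24 cytotoxic effectors, 10 were lower and 0 higher, median -0.38 (-0.52 to -0.33) below all random lists, with Gzmb at log2 -1.40 and Ifng at 5.83 against 15.03 CPM (log2 -1.37, -1.63 to -1.10). The median ran from -0.55 to -0.11 over the alternatives, and was -0.15 with a mitochondrial limit of 5%, -0.11 without doublet removal and -0.20 without the cytotoxic CD8 T subset. That subset held 3 of 6315 T cells with NanoCa and 26 of 5091 with mock (log2 -3.43, -5.79 to -1.72). Follicular helper T cells, which support germinal centres, made up 0.697% against 1.53% of T cells (log2 -1.14, -1.70 to -0.59). Naive T cells made up 20.6% against 8.96% (log2 1.21, 1.05 to 1.36), and the log2 ratio was 2.86 with cytotoxic and exhaustion genes left out of clustering, a setting chosen after the data were seen. Unnamed clusters held 62.1% and 72.7% of T cells, and large clusters lay mostly in a single library (288 against 1575 cells in cluster 0, 1406 against 178 in cluster 3). Clusters 0 and 3 both had the naive marker Igfbp4 among their leading genes but stayed unnamed. The naive share leaves them out, so these subset shares rest on how clusters were named. Exhaustion genes in T cells had 4 of 17 lower and 0 higher, including Lag3 (log2 -1.12), with a median of -0.15 (-0.23 to -0.0068, percentile 1.89). That median was above 0, between 0.013 and 0.097, under 7 alternatives, and interferon-gamma-induced genes in T cells had a median of 0.018 (-0.045 to 0.065, percentile 51.0). Cell cycle genes were lower in B cells, with 18 of 37 lower and 0 higher, median -0.55 (-0.69 to -0.42), among them Ube2c (log2 -1.24) and Cenpf (log2 -1.59), and the median was -0.26 in thinned cells and -0.27 with free RNA subtracted.

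Monocytes and macrophages of TDLN had lower levels of genes induced by interferon gamma, with 18 of 21 lower and 0 higher, median -1.15 (-1.29 to -1.03), which was -0.83 with the same cluster makeup. Lists named for other cell types moved both ways in this class. Cytotoxic effectors, which share Tnf, Ccl3 and Ccl4 with the inflammatory myeloid list, had 6 of 12 lower and 1 higher (median -0.60, -0.68 to -0.47, below all random lists). Naive and memory T-cell genes had 8 of 13 higher and 0 lower (median 0.95, 0.61 to 1.15, above all random lists). Exhaustion genes had a median of 0.48, and Ifng had 8 UMIs against 1. The T-cell attractant gene Cxcl9 was at 149 against 678 CPM (log2 -2.18), and Gbp4 at 46.4 against 147 CPM (log2 -1.67). Of 23 inflammatory myeloid genes 15 were lower and 0 higher, median -0.80 (-0.89 to -0.74), including Il1a (log2 -2.83) and Acod1 (log2 -2.31). Of 25 tissue-repair genes 9 were lower and 0 higher, median -0.39 (-0.45 to -0.28), including Arg1 (log2 -1.97) and Retnla (log2 -5.33), and the median was -0.23 with separate clustering and -0.83 in thinned cells. Glycolysis and hypoxia genes had a median of -0.73 with 14 of 19 lower. Each of these 4 medians lay below all random lists. MHC class II genes had a median of -0.47 (-0.51 to -0.43, percentile 0.04), which was -0.94 with at least 500 genes per cell and -0.71 in thinned cells. Interferon-stimulated genes had 11 of 49 higher and 3 lower, median 0.18 (0.14 to 0.28, percentile 99.3), with Slfn4 at log2 1.41 and Ly6a at -3.03. That median was 0.074 with TMM and 0.068 with median-of-ratios scaling, which lowered all ratios of this class by a log2 shift of -0.11. It was 0.37 with the same cluster makeup. Cluster 17 held 56.5% of these cells with NanoCa, while cluster 12 held 65.0% of those with mock, and their median depths were 2777 and 7378 UMIs.

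Mature DC of TDLN had higher MHC class II levels with NanoCa, 4 of 10 genes higher and 0 lower, median 0.50 (0.42 to 0.61, percentile 99.98), with H2-Ab1 at log2 0.74 and H2-Aa at log2 0.63. The median was 0.23 without doublet removal. Interferon-stimulated genes in these cells had 4 of 17 higher and 0 lower, median 0.26 (0.13 to 0.51, percentile 98.3), including Irf7 (log2 1.94), and the alternatives ran from 0.13 to 0.53. Of 23 genes of DC maturation, 2 were higher and 1 lower (median 0.046, -0.014 to 0.15), the checkpoint ligand gene Cd274 (log2 0.89), the costimulator gene Cd80 (log2 0.88) and the chemokine gene Ccl17 (log2 -0.74). NK cells of TDLN had Gzmc at log2 -2.21 and Gzmb at -1.13. Gzmf in these cells had 0 UMIs with NanoCa against 216 CPM with mock, 50.7-fold lower with the 0 set to the floor of 3 counts. Their cytotoxic effectors had 2 of 23 higher and 4 lower (median -0.12, percentile 8.99). Interferon-stimulated genes in NK cells had 1 of 37 higher and 5 lower, median -0.22 (-0.38 to -0.11, percentile 0.275), with Ly6a at log2 -1.02. In the same NK cells naive and memory T-cell genes were at a median of 0.47 (4 of 12 higher, 0 lower), DC maturation genes at 0.44 and regulatory T-cell genes at -0.60 (3 of 7 lower, 0 higher). The interferon median was 0.023 without doublet removal and -0.11 and -0.13 with mitochondrial limits of 5% and 20%.

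Xist-low Ptprc-low cells of TDLN also had lower levels of interferon-gamma-induced genes, 19 of 22 lower and 0 higher, median -1.97 (-2.17 to -1.80). Lymphocyte genes were higher in the same class, with 10 of 15 naive and memory T-cell genes higher and 1 lower (median 1.35, 1.04 to 1.42), 5 of 11 regulatory T-cell genes higher (median 0.51) and 8 of 16 germinal-centre and activated B-cell genes higher (median 0.48), and Ptprc was at 19.2 against 8.96 CPM. Gbp4 was at 8.32 against 68.2 CPM (log2 -3.04, -3.27 to -2.81), Iigp1 at 16.3 against 120 CPM (log2 -2.88) and Gbp2 at 89.5 against 545 CPM (log2 -2.61, -2.68 to -2.54). Of 22 MHC class I presentation genes 14 were lower and 0 higher, median -0.81 (-0.87 to -0.79), with Psmb9 at log2 -1.90. Both medians, and that of -0.15 (-0.22 to -0.044) for 47 interferon-stimulated genes, lay below all random lists, and the last was -0.23 with TMM scaling and -0.28 in thinned cells. Of the 3 clusters in this class, cluster 13 had 7 fibroblast markers enriched, with Ogn, Aspn and the marker Dcn among its leading genes. It held 79 of 339 cells with NanoCa and 175 of 1043 with mock. Its Rhox5 and Xist were at 334 and 5.78 CPM, against 11.7 and 252 CPM in the cluster named fibroblast. Genes higher with NanoCa in the class included the secreted factor genes Serpinf1 (190 against 47.6 CPM, log2 1.99, 1.92 to 2.07) and Grem1 (log2 1.92), a BMP antagonist, with Aspn (log2 1.48) and Gstm1 (log2 1.23). Tmem238 was lower (log2 -2.64). The genes lowest in T and B cells of TDLN were mostly lower in every class. Of 3507 genes measured in all 6 compared classes, 37 were lower in all and 4 higher in all, among them Bag1 (log2 -2.03 in T cells, -2.24 in B cells), Tmem160 (log2 -1.88 and -2.02), Hnrnpa0 (log2 -1.77 and -1.94) and Odc1 (log2 -2.00 in B cells). Glrx5 was at log2 -1.93 in T cells. In tumour T cells, 22 of the 37 were higher with NanoCa and 0 were lower, and 9 genes belonged to both sets.

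**Figure D3:**
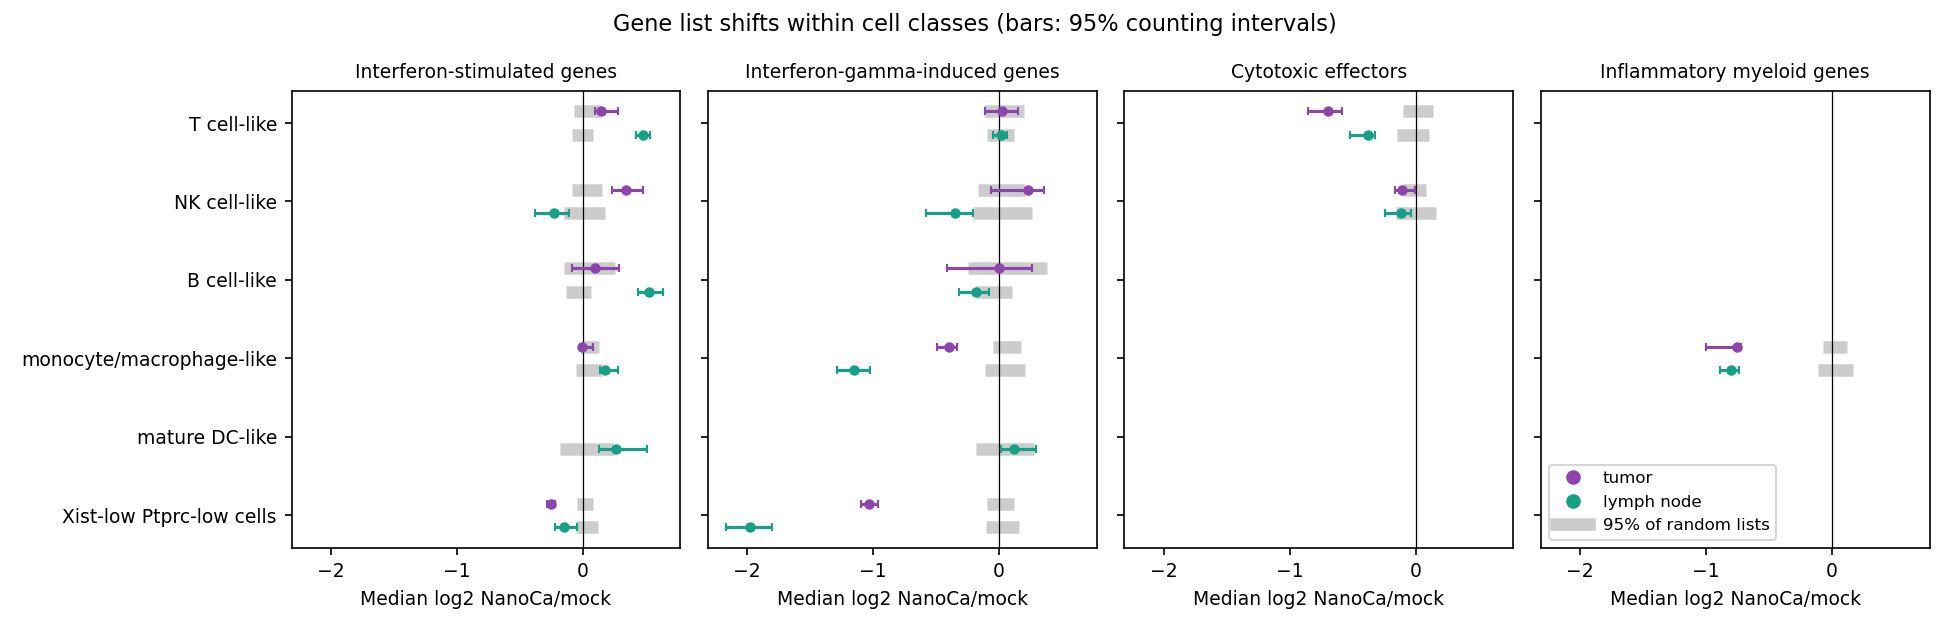
Median log2 ratio, NanoCa over mock, of 4 gene lists by class in tumour (purple) and TDLN (green); bars are 95% counting intervals and grey bars span the central 95% of 10000 matched random lists. Interferon-gamma-induced genes in Xist-low Ptprc-low cells stand at -1.03 in tumour and -1.97 in TDLN, and interferon-stimulated genes in TDLN T and B cells at 0.48 and 0.53.

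Side by side, both tissues had lower cytotoxic levels in T cells (medians -0.70 in tumour and -0.38 in TDLN, but 0.17 and -0.20 without the cytotoxic CD8 T subset), lower inflammatory levels in monocytes and macrophages (-0.75 and -0.80), and lower interferon-gamma-induced levels in monocytes and macrophages (-0.40 and -1.15) and in Xist-low Ptprc-low cells (-1.03 and -1.97). NK cell shares were lower in both (log2 -0.65 and -0.69), and B cell shares higher in both (0.55 and 0.43). The T cell share was lower in the tumour (log2 -0.58) and higher in TDLN (0.22, but 0.084 without the classes that lack Ptprc). Interferon-stimulated genes were at medians of 0.15 and 0.48 in T cells, 0.095 and 0.53 in B cells, and 0.34 and -0.22 in NK cells, where both signs turned without doublet removal (-0.10 and 0.023). Retnla in monocytes and macrophages was higher in the tumour (log2 5.56) and lower in TDLN (log2 -5.33, -7.62 to -3.76, on 3 and 204 UMIs). Calcium signalling genes, of interest for a calcium particle, had medians from 0.025 to 0.15 over the tumour classes and from -0.14 to 0.092 over the TDLN classes. The lowest was that of TDLN T cells (2 of 37 lower, 0 higher, percentile 0.04), and the other 10 medians lay within the central 95% of random lists.

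Other lists had these lowest and highest medians over the classes of each tissue. Genes of interferons, their receptors and nucleic-acid sensors ran from -0.10 to 0.11 in the tumour and from -0.059 to 0.21 in TDLN, with 0 medians outside the central 95% of random lists. Endoplasmic-reticulum stress genes ran from -0.14 to 0.26 and from -0.034 to 0.058, with 2 tumour and 0 TDLN medians outside that range of random lists, and lysosome and lipid genes from -0.097 to 0.19 and from -0.25 to -0.029, with 0 and 4 outside. Inflammasome and lytic cell death genes had their lowest tumour median in Xist-low Ptprc-low cells (-0.21) and their lowest TDLN median in monocytes and macrophages (-0.40, -0.53 to -0.31), with 1 tumour and 4 TDLN medians outside. Germinal-centre and activated B-cell genes ran from -0.16 to 0.38 and from -0.075 to 0.48, with 4 and 1 outside, and were at 0.19 in tumour B cells and 0.075 in TDLN B cells. Naive and memory T-cell genes ran from -0.20 to 0.30 in the tumour and from -0.024 to 1.35 in TDLN, highest there in Xist-low Ptprc-low cells, with 0 and 3 outside, and were at 0.10 in tumour T cells and 0.11 in TDLN T cells. No difference between tissues was tested.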

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

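These 5 pairs of values pointed opposite ways in tumour and TDLN, and the rule that picked them out was applied after they were seen. The T cell share had a log2 ratio of NanoCa to mock of -0.58 in the tumour and 0.22 in TDLN. Without the classes that lack Ptprc it had -0.59 and 0.084, and the TDLN denominator then still held 4.71% unnamed cells with NanoCa and 10.3% with mock. Fibroblasts, among cells sorted after a CD45 stain with a gate that is not given, had log2 ratios of share of 0.83 in the tumour and -1.17 in TDLN, and the tumour class held Krt18 at 188 CPM with NanoCa and 534 with mock. Monocytes and macrophages had 0.22 in the tumour and -0.54 in TDLN. Each of these ratios had a counting interval that excluded a ratio of 1 within its tissue, but the tumour value of monocytes and macrophages was 0.049 when each library was clustered on its own. The difference between tissues was not tested, because each group held 1 library.

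Interferon-stimulated genes in NK cells had a median log2 ratio of 0.34 in the tumour, above all 10000 random lists, and -0.22 in TDLN, at percentile 0.275. Without doublet removal the medians were -0.10 and 0.023, so the signs of both depended on that step. Tissue-repair genes in monocytes and macrophages had medians of 0.21 in the tumour and -0.39 in TDLN, with Retnla at log2 5.56 and -5.33. In TDLN these cells were spread over different clusters in the 2 libraries, cluster 17 holding 56.5% with NanoCa and cluster 12 holding 65.0% with mock. The differences between tissues were not tested here either.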

How the results depend on the processing

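Settings named as added, and the choice of results followed through all of them, were decided after the data were seen. A value held if it stayed within the 95% counting interval of the main value, moved if it left it, and turned if it changed sign from a main value that was called higher or lower (for a list, outside the central 95% of random lists). Interferon-stimulated genes in tumour monocytes and macrophages (-0.0062, percentile 3.21) were not called, so their changes of sign count as moved or held (0.019 with separate clustering). Of the main lists, 114 values held and 16 moved under the settings fixed in advance, and 15 held, 7 moved and 1 turned under added ones. Of the main shares, 78 held and 2 moved under the settings fixed in advance. Of the other lists, 324 values held, 72 moved and 7 turned under the settings fixed in advance, and 38 held, 18 moved and 3 turned under added ones. Of single-gene values, 471 held, 137 moved and 4 turned under the settings fixed in advance, with 93 of the moved ones from thinning, and 178 held, 25 moved and 1 turned under added ones. Xist-low Ptprc-low cells were taken to hold no free RNA, so its subtraction could not change their list and gene values. Those values are counted as held by construction. No paired analysis within a tissue was possible because each group held 1 library and groups shared replicate number 1 alone, and no test was run. Scrublet's automatic threshold called 0, 3, 360 and 2 barcodes, under 0.5% in 3 of 4 libraries, and was not run further. A class or T subset not named under a setting gave no value there. Values below are log2 ratios or list medians, and the cause was not tested unless given.

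Without doublet removal, interferon-stimulated genes were at -0.10 in tumour NK cells and 0.023 in TDLN NK cells, and exhaustion genes in TDLN T cells at 0.097, all of opposite sign to the main values. Exhaustion genes in TDLN T cells also turned with mitochondrial limits of 5% (0.035) and 20% (0.036), at resolution 2 (0.013) and with all variable genes (0.042).

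Interferon-stimulated genes in tumour monocytes and macrophages were at -0.061 at resolution 0.5, -0.038 at resolution 2, -0.037 with all variable genes, -0.089 with TMM, -0.082 with median-of-ratios scaling and 0.091 in thinned cells. The share of TDLN monocytes and macrophages was at -1.12 at resolution 0.5, and that of tumour ones at 0.049 with separate clustering. All variable genes gave 0.23 for interferon-stimulated genes in TDLN T cells and 0.13 in B cells. Separate clustering gave 0.54 for them in TDLN T cells, and -1.01 for interferon-gamma-induced genes in TDLN monocytes and macrophages. TMM and median-of-ratios scaling gave 0.079 and 0.073 for interferon-stimulated genes in tumour T cells.

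Thinning gave -0.35 for cytotoxic effectors in tumour T cells, -0.89 and -1.59 for interferon-gamma-induced genes in tumour and TDLN Xist-low Ptprc-low cells, and 0.66 for interferon-stimulated genes in TDLN B cells. It turned Ccna2 (0.60) and Rsad2 (0.012) in TDLN NK cells, Isg15 in mature DC (-0.60) and Cxcl9 in TDLN Xist-low Ptprc-low cells (1.62). The values of Ccna2 and Cxcl9 are those that equal counts in both libraries give, as when both sit at the floor. They then reflect only the numbers of thinned cells, 115 NK cells with NanoCa and 174 with mock. For Xist-low Ptprc-low cells these numbers were 334 and 1024. The value of Rsad2 can likewise arise from very few UMIs, so these sign changes do not show a reversal.

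Of the added settings, leaving out cytotoxic CD8 T cells turned cytotoxic effectors (0.17) and exhaustion genes (0.19) in tumour T cells and exhaustion genes in TDLN T cells (0.020), by construction through that subset. The same cluster makeup gave -0.072 for cytotoxic effectors in tumour T cells, 0.11 for interferon-stimulated genes in tumour monocytes and macrophages, -0.16 for these and -0.85 for interferon-gamma-induced genes in tumour Xist-low Ptprc-low cells, 0.047 for exhaustion genes in TDLN T cells and -0.83 for interferon-gamma-induced genes in TDLN monocytes and macrophages. Free RNA subtraction gave 0.65 and 0.85 for interferon-stimulated genes in TDLN T and B cells and turned Gbp2 in B cells (0.32). Leaving out unnamed clusters gave 0.15 for the TDLN T cell share.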

Other observations

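All tests in this part, and the ranking of genes relative to other classes, were chosen after the results were seen. Genes were ranked by their ratio minus the median of the other classes, and the values here are the ratios themselves. By that ranking tumour T cells had higher Id3 (log2 0.83), Tnfsf8 (log2 0.76) and the heat-shock gene Hspa1a (1036 against 443 CPM, log2 1.23). Tumour monocytes and macrophages had higher Smagp (log2 2.64, 1.24 above the other classes) and Tsc22d3 (log2 0.86, 0.66 above them), a glucocorticoid-induced gene, and lower Gadd45b (log2 -1.10). Xist-low Ptprc-low cells had higher Areg, which encodes the growth factor amphiregulin, in tumour (log2 0.65) and TDLN (log2 0.97). In TDLN, T cells had higher Gbp9 (log2 0.62) and Rnf213 (log2 0.70), and B cells higher Map3k8 (log2 0.81). Agtr1a was lower in both, at 124 against 210 CPM in T cells (log2 -0.76) and 35.0 against 68.4 CPM in B cells (log2 -0.97).

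Tumour NK cells had 4 of 8 MHC class II genes higher with NanoCa (median 0.76, 0.54 to 1.07), a list that antigen-presenting cells express most. TDLN monocytes and macrophages had 10 of 37 cell cycle genes higher and 1 lower (median 0.48, 0.34 to 0.58), while TDLN NK cells had 13 of 31 lower and 0 higher (median -0.36, -0.60 to -0.28). Ifng in TDLN NK cells was at 102 against 70.6 CPM (log2 0.53, 0.064 to 0.995), and in tumour NK cells at 144 against 163 CPM, with an interval that included a ratio of 1.

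The first pattern weighed was the 81 genes higher with NanoCa in every compared tumour class and the 37 lower in every compared TDLN class. Uneven recovery of GC-rich transcripts may raise or lower such a set. After the GC trend over all genes was taken off, the sets kept 96.4% and 95.9% of their median log2 ratios in T cells. That covers a broad trend over the GC content of each gene's longest transcript. It cannot decide on uneven recovery of the 3' fragments read here. The sets were picked for changes of at least 1.5-fold, so a weak trend could hardly lower them. Free RNA may carry 1 class's ratios into all others, but after its subtraction the sets kept 91.1% and 98.1%. In T cells of the other tissue, 29 genes of the tumour set and 22 of the TDLN set were called the opposite way, so that tumour NanoCa and TDLN mock stood together for them. A response common to all classes and a difference in how single libraries were made cannot be told apart with 1 library per group, and a second library per group would separate them.

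The second pattern was the lower share of Xist-low Ptprc-low cells in TDLN with NanoCa, 3.38% against 11.1%. Barcodes carried over from the tumour libraries may have produced them, but 1.92% (1.18 to 2.95) of the TDLN mock cells of this kind had a barcode found in a tumour library, against 2.91% of T cells. Droplets with free RNA alone would be shallow, but these cells had 12.3 times the median UMIs of T cells. Fibroblasts and endothelial cells, which also lack Ptprc, were together lower with NanoCa (log2 -1.53, -2.08 to -1.01, 42 and 114 cells), as would follow if the sort or dissection of the mock node let more such cells through, though the CD45 gate is not given. With Rhox5 at 403 and 355 CPM and Xist at 6.53 and 3.51 CPM these cells may be CT26 tumour cells, and whether the mock node held more of them in the animal stays open.

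The third pattern was the lower level of interferon-gamma-induced genes in Xist-low Ptprc-low cells. A different mix of their clusters may lower a list, but with the same cluster makeup 82.3% of the tumour median and 104.9% of the TDLN median remained. The clusters were built without the interferon lists, so a mix of states that differ in those genes alone is not covered. Less interferon gamma from lymphocytes may lower the list as well, and Ifng UMIs in T and NK cells per kept cell were lower in tumour (log2 -1.33, -1.55 to -1.11) and in TDLN (log2 -0.98, -1.21 to -0.76). These values are not corrected for depth and also follow the number of T and NK cells. As CPM of the class, Ifng was at log2 -0.59 in tumour and -1.37 in TDLN T cells. In NK cells it was at -0.18 (-0.53 to 0.17) in tumour and 0.53 in TDLN. Interferon-gamma-induced genes were also lower in monocytes and macrophages of tumour (-0.40) and TDLN (-1.15) and in TDLN NK cells (-0.35). They lay within the central 95% of random lists in tumour T (0.026) and B cells (-0.0024) and in TDLN T (0.018), B (-0.18) and mature DC (0.12). In tumour NK cells their median was 0.23 (-0.066 to 0.35, percentile 98.75), with 1 of 16 genes higher and 0 lower. Interferon gamma protein was not measured, and its part in the difference stays open.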
